A study of Homo sapiens with 18 samples.

How the data were processed

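Polyadenylated RNA was sequenced from H9, an established human embryonic stem cell line, and from cells differentiated from it. Per the labels, stem cells grew in Essential 8 medium, were moved to Essential 6 with retinoic acid (RA) and bone morphogenetic protein 4 (BMP4) for 7 days, and were then kept in a defined keratinocyte medium to day 50. Keratinocytes sorted from that culture were grown on collagen-peptide plates in the same medium and are called iKC here. Cells were detached with Accutase, RNA was taken with Trizol and RNeasy columns with DNase, and libraries were made with a KAPA mRNA kit, per the labels. The 18 libraries form 9 groups of 2. The series design text calls the duplicates biological, and p-values here, other than those of tests across genes, measure only the spread between those duplicates.

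The values are estimated counts that the authors deposited in 5 tables, each holding a knockout group and wild-type (WT) libraries. They are reads per gene in steps of 0.5, without scaling for depth or length. The submitters' processing notes name TopHat, HOMER, DESeq2 and the genome build hg38, with no role or version. Per the file headers, the stem cell table was counted with HOMER over exons, on both strands, with 1 transcript kept per gene and no depth adjustment. For the other 4 tables the counting command is not given in the sources used here. In the stem cell table reads of a gene and its antisense or overlapping partner cannot be told apart, as for FEZF1 and FEZF1-AS1, and for the others the strand setting is not known, as for H19 and HOTS or WT1 and WT1-AS. Which stage a table belongs to was read from the table's name and the labels, and 0 value columns were left unmatched. Tables held 28031 to 28035 usable genes, 28030 of them in every table. In all but the stem cell table, 27 symbols each had been turned into dates, of which 24 (day 50), 25 (day 7, AHDC1), 24 (day 7, GATA3) and 23 (iKC) were recovered by position and the rest left out. The day 7 WT libraries stand in both day 7 tables, with equal values for 98.75% and 98.78% of genes, and were counted once in joint fits. Gene coordinates are those of the tables, in hg38, for the transcript that the table lists.

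Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM normalization, quasi-likelihood F-test, Benjamini-Hochberg adjusted p with a threshold of 0.05. Each knockout group was compared with the WT libraries of its own table, 2 against 2, without a term for the replicate number. The AHDC1 KO and GATA3 KO groups of day 7 were compared in a fit of the 3 day 7 groups. Differences between stages in the knockout effect were interaction contrasts in a fit of all libraries. Joint fits used only genes with the same symbol and the same coordinates in each table joined, 25824 over all tables and 27617 at day 7, before the filter. Levels are CPM, counts scaled to library size, as mean ± SD with n = 2. Changes are log2 fold changes ± SE against WT. A value in which a group holds 3 or fewer reads is no bound. Against 0 reads a fold was computed from a floor of 3 reads over the group and is given as at least that fold, and for 1 to 3 whole reads the ratio of rounded counts over library totals is given with a 95% interval that covers counting error only.

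Lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 tested members, and again with an estimated correlation. The estimated form rests on the residual degrees of freedom of 2 against 2 libraries. Its smallest unadjusted camera p over all lists and comparisons was 0.0197. Hardly any list could pass after adjustment, so a call lost there does not decide whether a list moved. The 26 lists covered pluripotency, surface ectoderm and simple epithelium, basal keratinocyte, stratified differentiation, early mesoderm, mesenchyme and dermal fibroblast, basement membrane, the GATA family, HOX genes, the WNT pathway, the BMP and TGFB pathway, the retinoic acid response, DNA methylation machinery, CTCF and cohesin, imprinted genes, the PCDHB cluster, neural ectoderm, neural crest and melanocyte, endoderm, endothelium and blood, muscle, trophoblast and amnion, cell cycle, immediate early and stress genes, p53 targets and interferon response. Counts of members that passed are given over all tested genes, and those adjusted over the list alone are given or bounded. List medians were computed also with genes at the floor of 3 reads set to their bound, which changed none of them.

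Named genes followed a rule. It took AHDC1 and GATA3, the 6 genes with the largest rise and the 6 with the largest fall per comparison among genes past the threshold whose groups did not overlap and whose mean was at least 8 CPM, and the leading members of each list. Other genes are marked as named after their values were seen. Groups, tests, lists, the rule and the other settings were fixed before the data were examined. Alternatives were DESeq2 1.42.0, limma-voom, RLE or library-size scaling, no filter or a filter of 5 CPM in 2 libraries, robust hyperparameters, a fold threshold of 2, the replicate number as a block, a fit of all groups, fry for the lists, and leaving out each library. Joining tables by symbol alone, and the overlaps that involve GKO, were chosen after seeing the data.

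The code was tested on simulated counts with 200 changed genes per comparison. For a 2-fold change edgeR recovered 29.9% of genes in the stem cell table, 86.6% at day 7 for AHDC1 KO, 95.5% at day 7 for GATA3 KO, 94.0% at day 50 and 77.6% in iKC. At a 1.5-fold change recovery was 2.99%, 74.6%, 83.6%, 70.1% and 34.3%, in the same order. Averaged over 4 draws with gene-wise spread, false calls made up 4.60%, 6.90%, 4.97%, 7.70% and 16.3% of calls, above the threshold for day 7 AHDC1 KO, day 50 and iKC. With trended spread the shares were 4.99%, 3.74%, 4.74%, 5.03% and 4.98%, so this depends on the spread assumed. In the single draw used for recovery, false calls were 2 of 81, 20 of 193, 29 of 213, 21 of 195 and 20 of 160, above the threshold in all but the stem cell table. For the difference between day 50 and day 7, 37.3% of 2-fold differences were recovered.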

Results

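Gene expression was measured by sequencing polyadenylated RNA from H9 human embryonic stem cells (hESC) and from cells that H9 gave rise to on the way to keratinocytes, the main cell type of the epidermis. WT cells were sampled as hESC, at day 7 of RA and BMP4 treatment, at day 50, and as sorted keratinocytes (iKC). Cells labelled as knockouts (KO) of AHDC1, the gene of the protein Gibbin, were sampled at day 7, at day 50 and as iKC. Cells labelled as KO of GATA3, the gene of a zinc-finger transcription factor of surface ectoderm, were sampled at day 7, and a group labelled GKO as hESC. The labels do not spell out GKO, and the name is kept as it stands. Each of the 9 groups held 2 libraries. Reads counted in genes, in units of 1e6, numbered 15.75 and 18.46 in WT and 17.5 and 17.8 in GKO hESC. At day 7 they numbered 14.1 and 12.5 in WT, 22.4 and 19.5 in AHDC1 KO and 24.2 and 15.3 in GATA3 KO. Day 50 libraries held 30.05 and 24.8 (WT) and 31.8 and 27.6 (AHDC1 KO), and iKC libraries 68.8 and 49.9 (WT) and 52.2 and 52.5 (AHDC1 KO). The series title ties Gibbin to DNA methylation in mesoderm and to epithelial patterning, and the comparisons ask which genes differ when AHDC1 or GATA3 is disrupted at each stage.

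WT levels followed the stages named in the labels. POU5F1, a core pluripotency factor, stood at 1206 ± 186 CPM in hESC and at 0.0931 ± 0.0189 CPM at day 7. TFAP2A, a transcription factor of surface ectoderm, stood at 0.0271 ± 0.0383 CPM in hESC and 204 ± 6.47 CPM at day 7, where HAND1, a factor of lateral mesoderm and amnion, stood at 241 ± 2.68 CPM. COL1A1, a fibrillar collagen of mesenchyme, was at 3902 ± 247 CPM at day 7, 18217 ± 131 CPM at day 50 and 85.8 ± 12.8 CPM in iKC. The basal keratins KRT5 and KRT14 reached 1096 ± 43.3 and 88.6 ± 6.51 CPM at day 50 and 10264 ± 261 and 2083 ± 34.5 CPM in iKC. TP63, the master regulator of stratified epithelium, was at 32.5 ± 0.221 CPM at day 7, 23.3 ± 1.08 CPM at day 50 and 299 ± 20.02 CPM in iKC. These levels come from tables counted apart, so they are set side by side without a test.

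**Figure D1:**
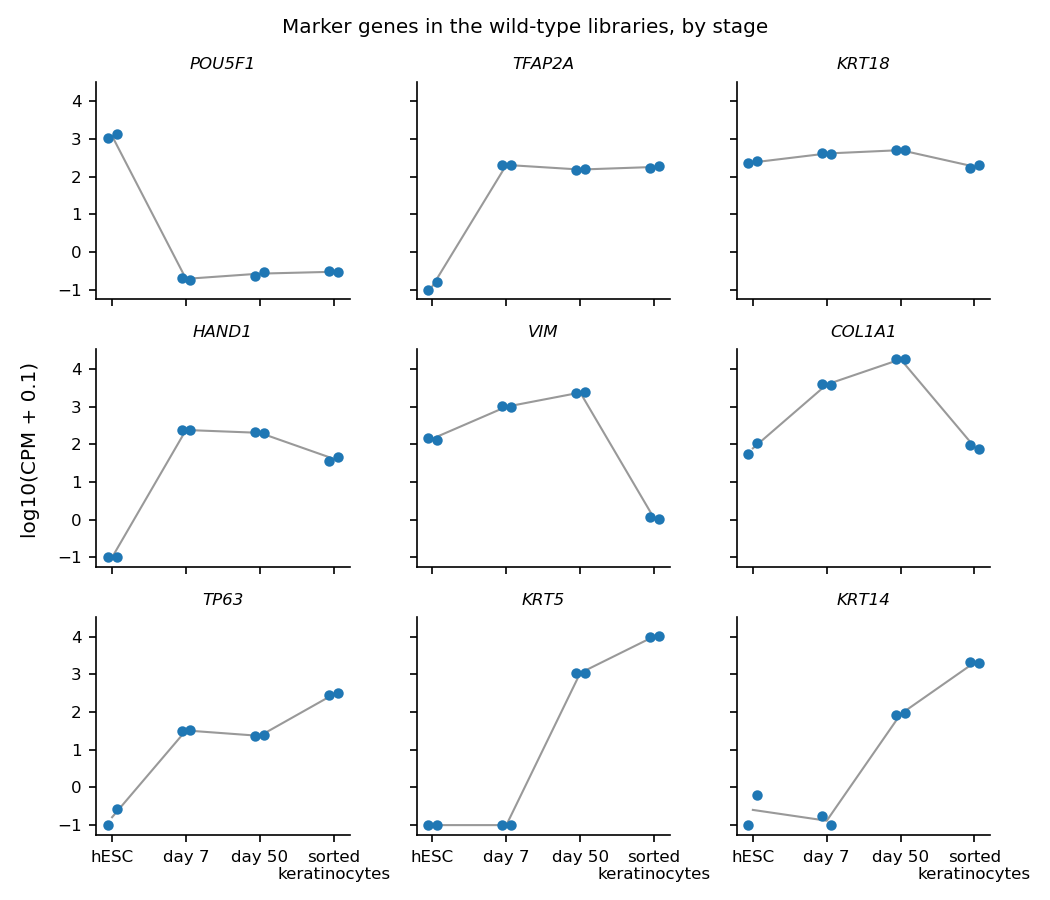
Levels of 9 marker genes in the WT libraries at the 4 stages, as log10 of CPM plus 0.1, with a point per library and a line through the group means. POU5F1 is high in hESC alone, COL1A1 and VIM are high at day 7 and day 50, and KRT5 and KRT14 are highest in iKC.

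The targeted genes were looked at first in every library. AHDC1 (chromosome 1, 27534245 to 27603494 in hg38) stood at 249 and 246 CPM in the day 7 WT libraries and 234 and 226 CPM in those labelled AHDC1 KO, a log2 change of -0.11 ± 0.04 (edgeR adjusted p = 0.0382). At day 50 it was at 220.0 and 231 CPM in WT and 196 and 187 CPM in AHDC1 KO (-0.20 ± 0.03, edgeR adjusted p = 1.05e-05), and in iKC at 141 and 139 against 114 and 118 CPM (-0.29 ± 0.08, edgeR adjusted p = 0.0545). In hESC it stood at 19.8 and 39.0 CPM in WT and 34.7 and 27.4 CPM in GKO (0.06 ± 0.29, edgeR adjusted p = 0.992), and in the day 7 libraries labelled GATA3 KO at 283 and 288 CPM (0.22 ± 0.03, edgeR adjusted p = 5.2e-05). GATA3 (chromosome 10, 8054704 to 8075201) was at 163 and 160.0 CPM in day 7 WT and at 224 and 217 CPM in the libraries labelled GATA3 KO, higher by 0.47 ± 0.03 (edgeR adjusted p = 3.23e-10). In the AHDC1 KO libraries GATA3 fell at day 7, to 126 and 125 CPM (-0.37 ± 0.04, edgeR adjusted p = 1.21e-05), rose at day 50, from 328 and 329.8 to 569 and 514 CPM (0.76 ± 0.04, edgeR adjusted p = 1.26e-09), and stood at 200.0 and 228 against 358 and 269.5 CPM in iKC (0.53 ± 0.16, edgeR adjusted p = 0.081). The hESC libraries held 0 and 1 GATA3 reads (WT) and 1 and 4 (GKO).

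Thus the mRNA of the targeted gene was higher than WT in the libraries labelled GATA3 KO and fell by 0.11 and by 0.20 on the log2 scale at day 7 and day 50 in those labelled AHDC1 KO. A frameshift or a small deletion can leave an mRNA in place, so counts over the whole gene do not check these labels, and each direction below is drawn between groups as labelled. The day 7 AHDC1 call in AHDC1 KO ended without WT replicate 2 (adjusted p = 0.145), AHDC1 KO replicate 1 (0.062) or replicate 2 (0.212), under DESeq2 (0.0562), with the replicate number as a block (0.0549), with library-size scaling (0.146) and in a fit of all groups (0.865). That fit also ended the AHDC1 call in GATA3 KO (0.385). In iKC both genes passed without AHDC1 KO replicate 2 (AHDC1 adjusted p = 0.0369, GATA3 adjusted p = 0.000778) and under DESeq2 (0.0249 and 0.0118). AHDC1 also passed with a filter of 5 CPM (0.0468) or robust hyperparameters (0.0497), and GATA3 without a filter (0.0269) or in a fit of all groups (0.00627).

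**Figure D2:**
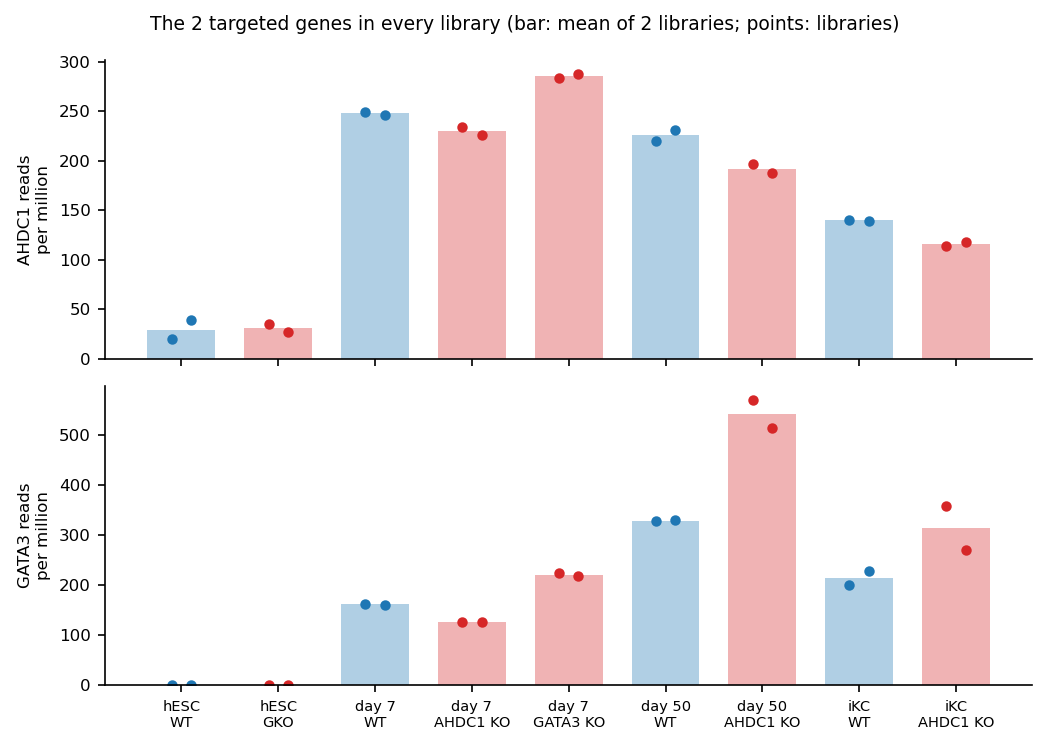
AHDC1 and GATA3 in CPM in each of the 9 groups, with bars for group means from 0 and a point per library. GATA3 libraries labelled GATA3 KO sit at 224 and 217 CPM, above the day 7 WT libraries at 163 and 160.0 CPM.

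In GKO hESC, few genes differed from WT, and those with the largest rises included genes of the early nervous system. NPTX1, a neuronal pentraxin (chromosome 17, 80466833 to 80476604), rose by 2.85 ± 0.26 from 14.0 ± 2.96 to 103 ± 3.72 CPM (edgeR adjusted p = 3.47e-07). The forebrain factor FEZF1 rose by 2.15 ± 0.26 (edgeR adjusted p = 2.09e-05) and the neural progenitor factor SOX21 by 1.85 ± 0.27. FGFR3, a fibroblast growth factor receptor, rose by 1.88 ± 0.26, and DUSP6, a phosphatase induced by such signalling, fell from 410.3 ± 20.7 to 142 ± 4.60 CPM (-1.55 ± 0.21, edgeR adjusted p = 0.000128 for both). PKIB, an inhibitor of protein kinase A (chromosome 6, 122471917 to 122726373), fell by 5.54 ± 0.46, from 17.1 ± 1.40 to 0.367 ± 0.196 CPM (edgeR adjusted p = 8.28e-08), as did ANKRD1, a nuclear factor of cardiac and stressed cells (-3.32 ± 0.36). CYP26A1, the enzyme that degrades retinoic acid, rose by 1.55 ± 0.27 to 40.4 ± 0.142 CPM, and TFAP2A was counted with 90.5 reads in GKO against 1 in WT, a ratio of 87.2 (15.3 to 3483). FEZF1-AS1, which overlaps FEZF1, rose by 2.24 ± 0.29, and its reads cannot be told from those of FEZF1.

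Of 15838 genes tested, 105 changed, 56 higher and 49 lower, and 103 of them by at least 2-fold. The gene lists held few of these. Of 21 pluripotency genes 1 rose and 1 fell, the latter LEFTY1 (-2.66 ± 0.47), and of 21 neural ectoderm genes 2 rose. Of 27 surface ectoderm genes 3 rose, of 18 genes of the retinoic acid response 1 rose and of 13 PCDHB genes 1 fell, PCDHB5 (-2.80 ± 0.55). Adjusted over the list alone, these counts were 1 and 3, 3 and 1, 4 and 1, 4 and 0, and 0 and 1. Camera called 7 lists, among them PCDHB, with a median of -0.49, and the retinoic acid response, neural ectoderm, WNT pathway, stress genes and p53 targets (adjusted p = 0.0176 each) and basement membrane (adjusted p = 0.000737). None held with an estimated correlation, where adjusted p was 0.530 for the first 6 and adjusted p = 0.589 for basement membrane. None of the tested DNA methylation (17), CTCF and cohesin (18), imprinted (22), neural crest (11), endoderm (7), muscle (14), trophoblast (5), cell cycle (24) and interferon (18) genes passed over all genes. Adjusted over the list alone, 2 neural crest genes and 1 trophoblast gene rose, and 1 CTCF and cohesin gene and 2 endoderm genes fell. Of 29 mesenchyme genes 0 rose and 2 fell (0 and 5 over the list alone), of 23 BMP and TGFB genes 1 and 2 (5 and 4) and of 11 endothelial and blood genes 0 and 1 (1 and 2). Over the list alone 2 of 10 stratified differentiation genes and 1 of 24 basement membrane genes rose and 2 of 22 stress genes fell, where none passed over all genes.

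The hESC libraries varied more than the others, with a biological coefficient of variation of 20.9% against 4.94%, 4.41%, 5.14% and 11.7% in the later comparisons, and 32.7% of genes had groups that did not overlap, where chance gives 33.3%. WT replicate 1 lay furthest from the other libraries (mean root mean square log2 distance 0.740, against 0.595 to 0.610). Without it 119 genes passed, without WT replicate 2 588, without GKO replicate 1 50 and without GKO replicate 2 49. The calls of NPTX1, FEZF1, SOX21, FGFR3, DUSP6, PKIB, ANKRD1 and CYP26A1 held in all 4 of these fits. The call of TFAP2A ended without GKO replicate 1 (adjusted p = 0.0688) or replicate 2 (0.155), that of LEFTY1 without GKO replicate 2 (0.116) and that of PCDHB5 without GKO replicate 1 (0.327). The list count dropped from 7 to 1 without WT replicate 2 and to 3 without GKO replicate 1, and without WT replicate 1 basement membrane (0.882) and retinoic acid response (0.0988) were lost. With no filter on low counts 218 genes passed, and in a fit of all groups 1253. Without that filter camera no longer called the WNT (adjusted p = 0.0555) or retinoic acid (0.0643) list.

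At day 7 in the AHDC1 KO libraries, most genes of the mesoderm and mesenchyme lists were lower and most of the surface ectoderm list higher than in WT. PDGFRA, a receptor of mesenchymal cells (chromosome 4, 54229089 to 54298247), fell by 2.54 ± 0.04, from 679 ± 13.2 to 117 ± 6.31 CPM (edgeR adjusted p = 1.15e-14), as did GATA4, a factor of heart and lateral mesoderm (-2.18 ± 0.05), and TWIST1, a mesenchymal factor (-1.56 ± 0.04). VIM, the intermediate filament of mesenchyme, fell from 1001 ± 37.4 to 213 ± 12.9 CPM (-2.24 ± 0.03, edgeR adjusted p = 1.36e-14), and WT1, a factor of mesothelium and kidney whose reads may include those of its antisense partner, fell by 4.90 ± 0.08. TP63 (chromosome 3, 189789660 to 189897279) rose from 32.5 ± 0.221 to 92.8 ± 4.39 CPM (1.51 ± 0.05, edgeR adjusted p = 3.12e-11), TFAP2C, a surface ectoderm factor, by 1.34 ± 0.05, and WNT6, a WNT ligand of surface ectoderm, by 2.09 ± 0.07. DSC3, a desmosomal cadherin of basal keratinocytes, went the other way (-1.04 ± 0.04).

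Of 16194 genes tested, 6903 changed (42.6%), 3392 higher and 3511 lower, and 508 were at least 2-fold higher and 897 at least 2-fold lower. In the mesenchyme list 23 of 29 members fell and 3 rose (median -0.68, camera adjusted p = 8.19e-09). In early mesoderm 16 of 23 fell and 5 rose (median -0.89, 1.27e-06), and in the GATA family 7 of 8 fell, GATA6 by 1.21 ± 0.05, and 1 rose (median -0.60, 7.29e-05). In the surface ectoderm list 25 of 30 rose and 4 fell (median 0.65, camera adjusted p = 8.19e-09), and in the basal keratinocyte list 18 of 21 rose and 3 fell (median 0.63, 3.22e-05). With an estimated correlation none of these calls held, adjusted p = 0.234 for each. In the stratified differentiation list 7 of 13 rose and 0 fell, PPL, a plakin of the cornified envelope, by 1.06 ± 0.04 (camera adjusted p = 0.0131, and adjusted p = 0.261 with an estimated correlation). In the BMP and TGFB list 14 of 30 fell and 6 rose, TGFB2 from 129 ± 2.62 to 10.5 ± 0.7001 CPM (-3.62 ± 0.05), with camera adjusted p = 0.00834 and adjusted p = 0.328 with an estimated correlation. Of 30 WNT genes 16 fell, SFRP1, a WNT antagonist, from 1755 ± 52.6 to 483 ± 13.4 CPM (-1.87 ± 0.02), and 10 rose (camera adjusted p = 0.0603).

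Other lists moved beside these. Of 13 endoderm genes 11 rose and 1 fell (median 3.89, camera adjusted p = 9.15e-07, and adjusted p = 0.234 with an estimated correlation). The list held 20 genes, of which 5 were tested in GATA3 KO against the same WT libraries. Members low in WT thus passed the filter on low counts only through high AHDC1 KO counts. Their rise, and with it the count and the median, was in part fixed by the filter, and 3 members had a group at 3 or fewer reads. Among the members that rose was FOXA1, a factor of endoderm and simple epithelia (3.89 ± 0.14, 1.74 ± 0.0417 to 26.3 ± 0.885 CPM, edgeR adjusted p = 4.86e-11), and LINC00261, a long noncoding RNA beside FOXA2, rose by 4.85 ± 0.11 and SHH by 3.70 ± 0.17. In the retinoic acid list 12 of 20 rose and 6 fell, CYP26A1 by 1.24 ± 0.05 (camera adjusted p = 0.0141, and adjusted p = 0.234 with an estimated correlation). Of 15 neural ectoderm genes 10 fell and 3 rose, NCAM1, a neural adhesion molecule, (-2.26 ± 0.05) (camera adjusted p = 0.0114). Of 17 muscle genes 9 fell and 2 rose (0.012). Of 23 stress genes 14 rose and 3 fell, with ATF3 up by 2.13 ± 0.04 (0.000107), and of 20 p53 targets 14 rose and 1 fell (6.95e-05). With an estimated correlation adjusted p was 0.234 for these 4. Of 11 pluripotency genes 7 rose and 2 fell (camera adjusted p = 0.0196, and adjusted p = 0.270 with an estimated correlation). The call ended with no filter on low counts (camera adjusted p = 0.188), and without WT replicate 1, WT replicate 2 or AHDC1 KO replicate 2. Of 17 genes of the DNA methylation machinery 7 rose and 2 fell (camera adjusted p = 0.086). Of 23 imprinted genes 6 rose and 9 fell, DLK1 from 1347 ± 51.9 to 281 ± 14.5 CPM (0.085). Of 18 CTCF and cohesin genes 2 rose and 3 fell (0.989) and of 15 PCDHB genes 2 rose and 2 fell (0.771). Of 23 basement membrane genes 9 rose and 11 fell, of 19 HOX genes 10 and 4, of 12 neural crest genes 2 and 5, of 7 endothelial and blood genes 0 and 3, of 10 trophoblast genes 4 and 3, of 24 cell cycle genes 4 and 3, and of 17 interferon genes 5 and 6, none called by camera. Adjusted over the list alone, counts moved by at most 2 members, the largest move being the cell cycle list, with 2 and 2. The WNT list was called with no filter on low counts (camera adjusted p = 0.0444), and without WT replicate 2 or AHDC1 KO replicate 2. DESeq2 called 4081 genes, and a fit of all groups 2073, in which the GATA3 fall did not pass (adjusted p = 0.0991).

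In the day 7 libraries labelled GATA3 KO, whose GATA3 mRNA was above WT, most genes of the mesoderm and mesenchyme lists were again lower and most of the surface ectoderm list higher. PDGFRA fell to 63.7 ± 0.294 CPM (-3.40 ± 0.04, edgeR adjusted p = 4.54e-19), as did GATA4 (-3.37 ± 0.05) and VIM (-2.72 ± 0.04). TBX18, a T-box factor of mesenchyme and epicardium, fell from 41.4 ± 0.853 to 0.670 ± 0.0693 CPM (-5.94 ± 0.14). TP63 rose to 150.4 ± 0.616 CPM (2.23 ± 0.04, edgeR adjusted p = 1.49e-16), and COL17A1, a hemidesmosomal collagen of basal keratinocytes (chromosome 10, 104031288 to 104085880), by 3.42 ± 0.08, from 5.85 ± 0.605 to 62.1 ± 0.502 CPM (edgeR adjusted p = 3.9e-15). Among genes with a mean of at least 8 CPM, the rises were led by CSRP1, a LIM protein of the actin cytoskeleton, at 5.16 ± 0.0780 in WT and 170 ± 0.867 CPM in GATA3 KO (5.05 ± 0.06, edgeR adjusted p = 4.54e-19).

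Of 15951 genes tested, 8538 changed (53.5%), 4194 higher and 4344 lower, with 614 and 1276 at least 2-fold. In the mesenchyme list 24 of 29 fell and 3 rose (median -0.92, camera adjusted p = 5.08e-09), and in early mesoderm 20 of 23 fell and 2 rose (median -2.03, 4.54e-11). Of 30 surface ectoderm genes 28 rose and 1 fell (median 0.74, 7.27e-14). Of 20 basal keratinocyte genes 17 rose and 2 fell (median 0.84, 1.03e-05), of 13 stratified differentiation genes 8 rose and 0 fell (0.0069) and of 8 GATA family genes 5 fell and 1 rose (0.00234). Of 18 HOX genes 12 fell, HOXA5 by 1.43 ± 0.08, and 4 rose (0.0169). Of 15 neural ectoderm genes 11 fell, DCX, a microtubule protein of migrating neurons, from 641 ± 2.64 to 209 ± 1.46 CPM, and 2 rose (0.00133). Of 23 imprinted genes 14 fell and 4 rose (0.0189), and of 23 stress genes 16 rose and 3 fell (0.00026). Of 11 pluripotency genes 8 rose and 2 fell (0.0293), with a median of 0.19 and a mean of -0.08, and of 24 cell cycle genes 9 rose and 0 fell (0.0292). None of these 12 calls held with an estimated correlation, adjusted p = 0.345 for each, and the last 2 ended without GATA3 KO replicate 2. The pluripotency call also ended with no filter on low counts (camera adjusted p = 0.0986).

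The remaining lists were not called. Of 29 WNT genes 10 rose and 16 fell, with SFRP1 down by 3.08 ± 0.03, of 29 BMP and TGFB genes 9 and 15, with TGFB2 down by 4.39 ± 0.06, and of 18 retinoic acid genes 8 and 8, CRABP2, a retinoic acid binding protein, up by 0.96 ± 0.03. DNA methylation genes numbered 7 up and 3 down of 17, CTCF and cohesin 8 and 2 of 18, with STAG2 up by 0.97 ± 0.03, PCDHB 0 and 6 of 15, basement membrane 8 and 10 of 23, neural crest 3 and 5 of 11, endoderm 0 and 3 of 5, endothelial and blood 3 and 2 of 6, muscle 4 and 9 of 16, trophoblast 5 and 2 of 11, p53 targets 7 and 5 of 20 and interferon 9 and 3 of 17. With no filter on low counts camera called the BMP and TGFB (adjusted p = 0.0359), WNT (0.0486), DNA methylation (0.0384) and muscle (0.0225) lists. The muscle list was also called without WT replicate 1, WT replicate 2 or GATA3 KO replicate 1. CTCF and cohesin was called without WT replicate 1 and DNA methylation without WT replicate 2. Adjusted over the list alone, counts moved by at most 2 members. DESeq2 called 5244 genes and a fit of all groups 3215.

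Set against each other, the 2 knockouts of day 7 shared part of their changes and differed in others. Of 15824 genes tested in both, 2191 were higher in both and 2563 lower in both, where independent lists would share 854 and 958, and 479 went opposite ways (1809 for independent lists). VIT, a matrix protein, rose by 3.13 ± 0.19 in AHDC1 KO and 3.73 ± 0.16 in GATA3 KO, ANKRD1 by 3.49 ± 0.09 and 3.04 ± 0.11, and PKHD1L1 fell in both (-5.88 ± 0.24 and -5.78 ± 0.21). Both comparisons used the same 2 WT libraries. Groups simulated without changes, against drawn WT libraries that both shared, gave 0.55 genes higher in both and 0.1 lower in both. Their changes correlated at 0.605 (0.574 to 0.626 over 20 simulations), beside 0.659 observed across genes. The same sign was found for 69.8% of genes, beside 75.4% observed. In groups without changes a shared control alone gives such a correlation and share, so neither value by itself shows how alike the knockouts are. The covariance, which keeps the size of the changes, was 0.357 against 0.0143 simulated, a difference of 0.342. Most of the covariance was thus not reproduced by a shared control. The simulation held no changed genes and the controls cannot be split, so part of the excess of shared calls may come from the controls. In the direct test 6724 of 16273 genes differed between the knockouts, 3430 higher in AHDC1 KO and 3294 lower. FOXA1 was higher in AHDC1 KO by 5.97 ± 0.16, SHH by 7.02 ± 0.23 and EMX2OS by 6.45 ± 0.13, while CSRP1 was lower by 6.75 ± 0.07 (log2 -6.75, edgeR adjusted p = 2.36e-21). LINC00261 had 0 reads in GATA3 KO and 2017 in AHDC1 KO. DESeq2 found 3957 genes that differed and 2768 shared calls.

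At day 50 in the AHDC1 KO libraries, most surface ectoderm genes were above WT, while most genes of the stratified differentiation, mesenchyme, WNT and BMP and TGFB lists were lower. VTCN1, a surface protein of simple epithelia (chromosome 1, 117143587 to 117210960), rose from 274 ± 5.70 to 1071 ± 49.3 CPM (2.004 ± 0.04, edgeR adjusted p = 2.15e-14), TFAP2A by 1.03 ± 0.02 and KRT13, a keratin of mucosal epithelium, by 3.75 ± 0.07. COL7A1, the collagen of anchoring fibrils (chromosome 3, 48564073 to 48595160), fell from 536 ± 10.8 to 61.3 ± 5.33 CPM (-3.09 ± 0.04, edgeR adjusted p = 3.29e-16), as did the desmosomal cadherins DSG1 (-3.07 ± 0.06) and DSG3 (-1.79 ± 0.03) and LAMA3, a laminin chain of the epidermal junction (-2.01 ± 0.04). KRTDAP, a protein of differentiating keratinocytes, fell by 5.70 ± 0.15, as did AGR2, a disulfide isomerase of secretory epithelium (-8.48 ± 0.11). COL1A1 fell from 18217 ± 131 to 8348 ± 602 CPM (-1.09 ± 0.02), as did GREM1, a BMP antagonist (-2.46 ± 0.04). KRT5 did not pass (0.01 ± 0.04), and KRT14 fell by 0.96 ± 0.04, both named after their values were seen.

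Of 17119 genes tested, 9811 changed (57.3%), 4757 higher and 5054 lower, with 707 and 1754 at least 2-fold. In the mesenchyme list 28 of 34 fell and 5 rose (median -0.98, camera adjusted p = 4.49e-08), in early mesoderm 12 of 23 fell and 4 rose (-0.60, 0.000445). In stratified differentiation 20 of 32 fell and 6 rose (-0.71, 0.000206), and in the BMP and TGFB list 22 of 32 fell, BMP5 from 142 ± 1.71 to 33.9 ± 1.13 CPM, and 7 rose (-0.78, 6.88e-05). Of 32 WNT genes 21 fell, LGR5, a WNT receptor partner of hair follicle and gut stem cells, by 2.50 ± 0.11, and 6 rose (0.00504). Of 26 HOX genes 16 fell and 4 rose (0.00668), and of 12 neural ectoderm genes 7 fell and 2 rose (0.0327). In the surface ectoderm list 25 of 30 rose and 2 fell (0.79, 9.39e-10). Of 24 cell cycle genes 17 rose and 1 fell (0.00158), and of 20 p53 targets 16 rose and 1 fell, with BTG2, an antiproliferative p53 target, up by 1.40 ± 0.03 (2.77e-05). With an estimated correlation adjusted p was 0.512 for each of these. Of 27 basal keratinocyte genes 16 fell and 7 rose (0.0323). Of 25 basement membrane genes 15 fell and 7 rose (0.0495), and of 10 endoderm genes 7 rose, TTR, a transport protein of liver, by 3.97 ± 0.20, and 1 fell (0.0391). Their adjusted p values with an estimated correlation were 0.657, 0.512 and 0.626. The basal and basement membrane calls ended without AHDC1 KO replicate 2, and basement membrane also with the replicate number as a block (camera adjusted p = 0.068). The neural ectoderm call ended with no filter on low counts (camera adjusted p = 0.0679) and without AHDC1 KO replicate 1. The endoderm call ended without WT replicate 1 or AHDC1 KO replicate 1.

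Lists that were not called at day 50 also held changed members. Of 17 DNA methylation genes 9 rose, ZBTB38, a reader of methylated DNA, by 0.33 ± 0.03, and 3 fell. Of 18 CTCF and cohesin genes 11 rose and 4 fell, CTCFL, the CTCF paralog of germ cells, by 2.66 ± 0.14, and of 26 imprinted genes 10 rose and 13 fell. IGF2, an imprinted growth factor, rose from 38744 ± 223 to 53519 ± 3075 CPM. H19, its imprinted neighbour, stood at 0.441 ± 0.624 CPM in WT and 63.9 ± 28.8 CPM in AHDC1 KO (7.09 ± 0.54), and the overlapping HOTS at 0.770 ± 0.347 and 23.0 ± 20.6 CPM, so their reads may be shared. With robust hyperparameters neither call held (adjusted p = 0.0504 and 0.153). Of 15 PCDHB genes 9 fell and 0 rose (camera adjusted p = 0.0554). Camera called this list with the block (adjusted p = 0.0199), with no filter on low counts (0.0221), with RLE scaling (0.0484) and without AHDC1 KO replicate 2. Of 12 pluripotency genes 4 rose and 3 fell, of 7 GATA family genes 3 and 3, with GATA4 at 0.274 ± 0.0113 in WT and 3.50 ± 0.149 CPM in AHDC1 KO, of 21 retinoic acid genes 11 and 7, ALDH1A2, which makes retinoic acid, up by 2.78 ± 0.07, of 13 neural crest genes 4 and 4, of 13 endothelial and blood genes 3 and 6, of 19 muscle genes 6 and 9, of 11 trophoblast genes 6 and 3, of 23 stress genes 14 and 7 and of 25 interferon genes 10 and 6. Adjusted over the list alone, counts moved by at most 2 members. CAT, the gene of catalase, was counted with 0.5 reads in AHDC1 KO and 1035 in WT. A fit of all groups called 4280 genes, with the AHDC1 fall no longer passing.

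In iKC, part of the mesenchyme and of the BMP and TGFB genes were lower in AHDC1 KO, and markers of keratinocyte differentiation moved in both directions. SULF1, a sulfatase of heparan sulfate, fell from 50.3 ± 5.31 to 0.205 ± 0.0616 CPM (-7.98 ± 0.21, edgeR adjusted p = 6.93e-05), as did PPP1R9A, an actin-binding protein (chromosome 7, 94907637 to 95296415; -8.18 ± 0.24), and NT5E, a mesenchymal ectonucleotidase (-5.72 ± 0.17). BMP5 fell from 23.6 ± 0.863 to 0.525 ± 0.124 CPM (-5.51 ± 0.19, edgeR adjusted p = 8.6e-05), as did ID1, a direct BMP target (-3.28 ± 0.12), and TGFB2 (-3.50 ± 0.16). COL7A1 fell from 984 ± 74.7 to 210 ± 39.1 CPM (-2.25 ± 0.17, edgeR adjusted p = 0.000566), as did DSG3 (-1.21 ± 0.11). KRT1, a keratin of suprabasal cells, rose from 22.7 ± 0.865 to 58.0 ± 1.40 CPM (1.33 ± 0.08), WNT3, a WNT ligand, by 1.81 ± 0.09, and among genes with a mean of at least 8 CPM the rises were led by HTRA1, a secreted protease (chromosome 10, 122461525 to 122514908), from 0.456 ± 0.0344 to 17.8 ± 2.69 CPM (5.23 ± 0.19, edgeR adjusted p = 8.6e-05), and the alarmin IL33 (5.16 ± 0.30). TWIST1 was counted with 1.5 reads in AHDC1 KO and 317 in WT, and ZEB2, a repressor of epithelial genes, with 2 and 349, a ratio of 154 (42.3 to 1277.5).

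Of 15995 genes tested, 2642 changed (16.5%), 1056 higher and 1586 lower, with 399 and 950 at least 2-fold. In the mesenchyme list 13 of 31 fell and 1 rose (median -1.06, camera adjusted p = 4.8e-11), and adjusted over the list alone 17 and 1. Of 25 BMP and TGFB genes 11 fell and 1 rose (-0.87, 3.35e-15), adjusted over the list alone 14 and 2. Of 23 imprinted genes 8 fell and 0 rose, with PEG10, an imprinted retrotransposon-derived gene, from 698 ± 62.7 to 109 ± 16.3 CPM (0.000532), adjusted over the list alone 11 and 1. With an estimated correlation adjusted p was 0.395 for these 3. Of 24 interferon genes 8 rose, OAS3, an antiviral synthetase, by 1.63 ± 0.12, and 1 fell (0.000532, and adjusted p = 0.406 with an estimated correlation). Of 24 cell cycle genes 7 fell and 0 rose, and adjusted over the list alone 14 and 1 (0.0142). Of 23 stress genes 5 fell and 0 rose (0.0425) and of 20 p53 targets 5 rose and 0 fell (0.0425), with adjusted p = 0.990 with an estimated correlation for the 3. The cell cycle and p53 calls ended without WT replicate 2 (0.146 for both) or AHDC1 KO replicate 1 (0.0608 and 0.165), the p53 call also with the block (0.0528), and the stress call without WT replicate 2 (0.0694) or AHDC1 KO replicate 2 (0.124).

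The keratinocyte lists were not called in iKC. Of 27 basal genes 7 rose and 3 fell, adjusted over the list alone 9 and 3, with KRT14 up by 0.96 ± 0.13 and TP63 by 0.48 ± 0.10, both named after their values were seen. Of 34 stratified differentiation genes 7 rose and 3 fell (camera adjusted p = 0.122, and 2.27e-09 without AHDC1 KO replicate 1), and of 30 surface ectoderm genes 2 rose and 8 fell, TFAP2B from 13.0 ± 0.902 to 1.20 ± 0.390 CPM. Of 23 basement membrane genes 10 rose, NID1, a nidogen, by 3.74 ± 0.14, and 5 fell. Of 22 WNT genes 6 rose and 4 fell, SFRP2 down by 5.08 ± 0.27, of 14 early mesoderm genes 6 and 4, and of 6 GATA family genes 2 and 1, TRPS1, a GATA-type repressor of hair and bone, down by 3.09 ± 0.13. Retinoic acid genes numbered 4 up and 5 down of 15, HOX 1 and 1 of 14, DNA methylation 0 and 1 of 17, CTCF and cohesin 0 and 1 of 17, PCDHB 0 and 3 of 13, neural ectoderm 1 and 3 of 6, neural crest 1 and 0 of 8, muscle 0 and 2 of 10, trophoblast 0 and 1 of 8 and pluripotency 1 and 1 of 8. Adjusted over the list alone, interferon numbered 11 and 2 and WNT 9 and 5, and the lists without a second count here moved by at most 2 members. The AHDC1 KO libraries lay further apart (0.428) than the WT libraries (0.264, root mean square log2 distance). Without WT replicate 1 626 genes passed, without WT replicate 2 583 and without AHDC1 KO replicate 1 4066, and a filter of 5 CPM left 1652.

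**Figure D3:**
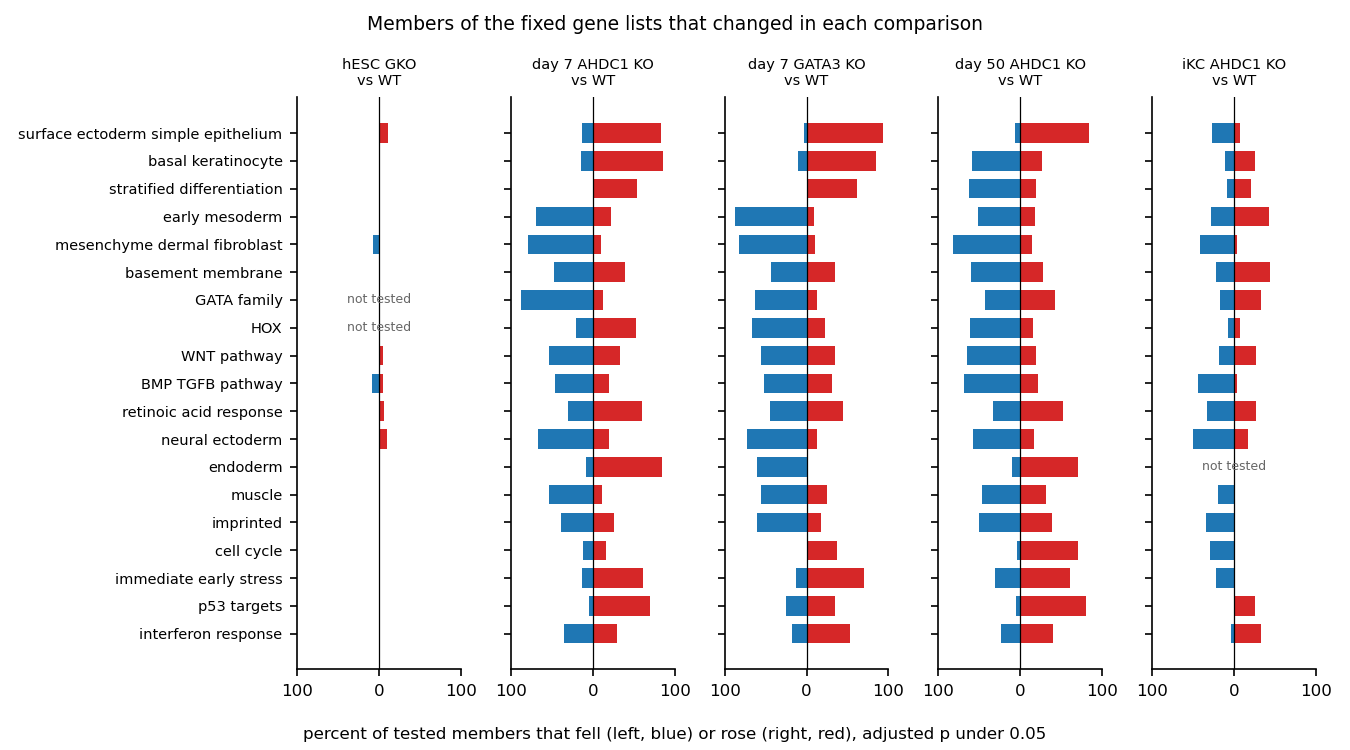
Percent of tested members of 19 gene lists that fell (to the left) or rose (to the right) in each of the 5 comparisons. Mesenchyme members fell in 23 of 29, 24 of 29, 28 of 34 and 13 of 31 cases at day 7 in AHDC1 KO and GATA3 KO, at day 50 and in iKC.

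Across stages, the effect of the AHDC1 KO label overlapped in part. Between day 7 and day 50, 1498 genes were higher in both and 1780 lower in both (929 and 967 for independent lists), and 1398 went opposite ways (1896). Between day 7 and iKC the counts were 302 and 601 (186 and 280), with 493 opposite (473), and between day 50 and iKC 480 and 987 (290 and 409), with 512 opposite (712). In all 3 comparisons 183 genes were higher and 482 lower, where independent lists would share 54.5 and 74.0. GRHL3, a factor of epidermal barrier formation, rose by 1.995 ± 0.16 at day 7, 2.19 ± 0.10 at day 50 and 2.75 ± 0.42 in iKC, and CCBE1, a matrix protein of lymphatic growth, by 1.52, 3.17 and 1.65. The zinc-finger gene ZNF583 was at least 43.0-fold lower at day 7, 97.6-fold at day 50 and 129-fold in iKC, with 0 reads in each AHDC1 KO group, and CAT at least 165-fold at day 7 and 289.95-fold in iKC. CAT was also lower in the day 7 libraries labelled GATA3 KO (log2 -4.58). DESeq2 found 1922 genes shared by day 7 and day 50.

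Tested directly, the effect differed between stages for 1865 of 16996 genes from day 7 to day 50, for 2255 from day 50 to iKC and for 1952 from day 7 to iKC. For 838 of the 1865 the effect was higher at day 50, by a larger rise, a smaller fall or a rise in place of a fall. GATA4 fell at day 7 and rose at day 50, a difference of 5.90 ± 0.25 (edgeR adjusted p = 9.16e-10), and KRTDAP was lower at day 50 and higher in iKC, a difference of 8.22 ± 0.50 (edgeR adjusted p = 1.51e-08). GATA3 differed by 1.15 between day 50 and day 7. With genes joined by symbol alone, the effect differed from day 7 to day 50 for 2197 genes. Without a single library the count from day 7 to day 50 lay between 1213 and 1296, with 1213 without WT day 50 replicate 1, 1214 without WT day 7 replicate 1, 1216 without AHDC1 KO day 50 replicate 1, and 1235 and 1239 without AHDC1 KO day 7 replicate 1 and 2.

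Genes called in GKO hESC were also set against the later comparisons, an overlap chosen after seeing the data. Of the genes lower in GKO, 22 were lower in AHDC1 KO at day 7, 29 at day 50 and 24 in iKC, where independent lists would share 8.17, 12.4 and 3.42, and 14 were lower in GATA3 KO (12.0). Genes higher in both numbered 13, 12, 5 and 15 in the same order (9.27, 12.1, 1.73 and 11.7). Calls in opposite directions numbered 29, 28, 9 and 53 (17.5, 24.5, 4.90 and 23.6), at day 7 more than the shared falls. Of 21 genes at least 8-fold lower in GKO hESC, 15 of the 20 tested at day 50 were at least 8-fold lower in AHDC1 KO, against 0.381% of other genes (Fisher's exact test across genes, p = 5.49e-32). By Fisher's exact test across genes, the counts were 8 of 14 at day 7 (0.378%, p = 2.24e-16), 11 of 16 in iKC (1.32%, p = 1.18e-17) and 1 of 20 in GATA3 KO (0.789%, p = 0.148). These tests took genes as independent, although some, such as ZNF582 and ZNF582-AS1, may share reads. Their p-values do not measure the spread between libraries, and the other genes were not matched for level. The 1 in GATA3 KO was CAT (log2 -4.58). There 17 were higher than WT, in part genes low in WT that passed the filter only through high GATA3 KO counts. CSRP1, 1 of the 17, had 0 reads in GKO hESC, at least 69.8-fold below WT.

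**Figure D4:**
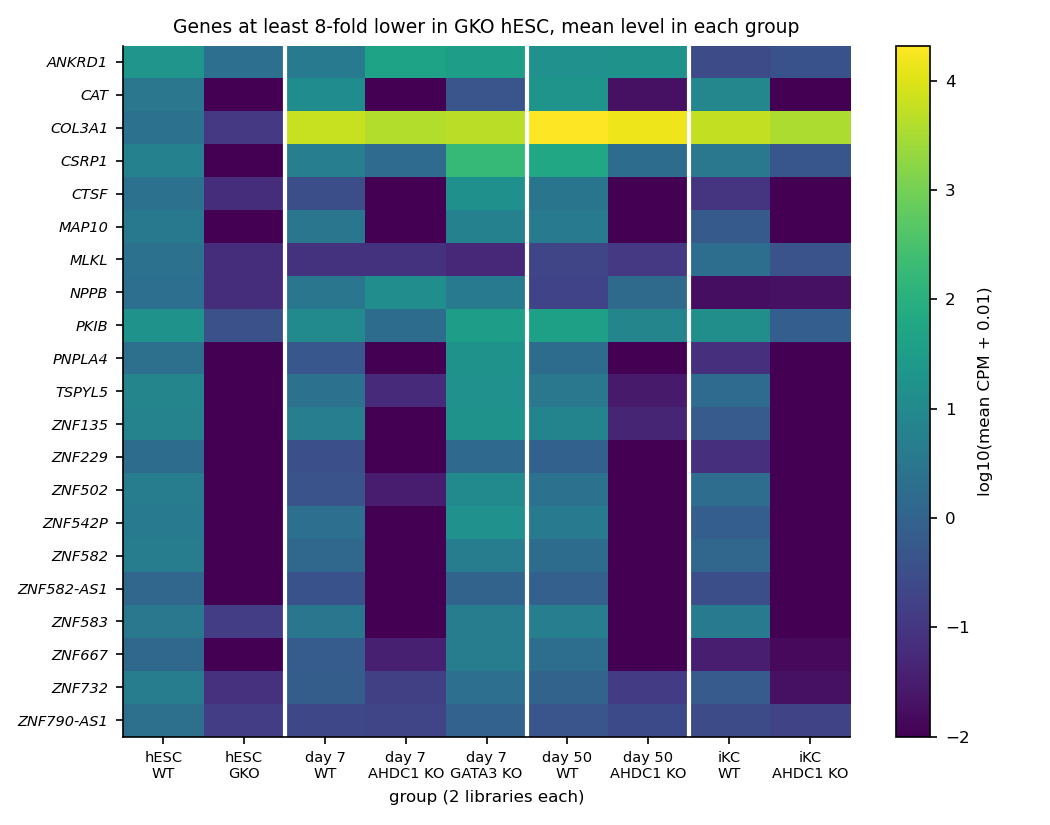
Heat map of log10 of mean CPM plus 0.01 for the 21 genes at least 8-fold lower in GKO than in WT hESC, over the 9 groups of 2 libraries. Most are near 0 in the GKO and AHDC1 KO groups, and 1 of 20 tested, CAT, was at least 8-fold lower in the GATA3 KO group.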

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

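The tests of stage differences were planned, and the tests of explanations for the mesoderm and endoderm genes were chosen after the result was seen. The results below drew attention because the knockout effect differed between stages by a direct test, each value being a difference of log2 changes from edgeR. Differences in which a group held 3 or fewer reads are fitted values and no bound, and they are named as such.

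From day 7 to day 50, the AHDC1 KO effect differed for 1865 genes. It was higher at day 50 for HCN4, a pacemaker channel (6.54), GATA4 (5.90) and LIN7A (4.19), and as a fitted value for SCG3 (6.09, with 0 reads in day 50 WT), whose call ended without WT day 50 replicate 1 or 2 or AHDC1 KO day 50 replicate 2 (adjusted p = 0.105, 0.075 and 0.0648) and with the replicate number as a block (0.0602). It was lower for KRTDAP (-6.29) and EMX2OS (-5.11), and as fitted values for AGR2 (-8.78, 2 reads in day 7 WT) and GABRB2 (-4.94, 3 reads in day 50 AHDC1 KO). Among list members it differed for GATA3 (1.15), GABRP (1.98), WNT6 (-0.89) and NCAM1 (0.94).

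From day 50 to iKC, the effect differed for 2255 genes. It was higher in iKC for the cornification genes KRTDAP (8.22), SBSN (6.40) and SPRR1B (4.86) and for HTRA1 (5.69), and lower for GUCY1A2 (-8.45) and SHISA2 (-7.10), and as fitted values for TMEM176A (-8.06, 0.5 reads in iKC AHDC1 KO) and POSTN (-7.34, 0 reads there). Among list members it differed for DSG3 (0.52), GATA4 (-2.89), TRPS1 (-2.21), SFRP2 (-3.76), LGR5 (-2.48), BMP5 (-3.53) and BTG2 (-0.57).

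From day 7 to iKC, the effect differed for 1952 genes. It was higher in iKC for POU3F1 (5.15) and TBX18 (4.66), and as fitted values for ANXA8 (5.49, 1 read in day 7 AHDC1 KO) and WIPF3 (5.25, 0 reads in iKC WT). The ANXA8 call ended without WT day 7 replicate 2 (adjusted p = 0.395), AHDC1 KO day 7 replicate 1 or 2 (0.175 and 0.149), WT iKC replicate 1 or 2 (0.0702 and 0.0732) or AHDC1 KO iKC replicate 1 (0.0552), and the WIPF3 call without AHDC1 KO iKC replicate 2 (0.24). It was lower for GUCY1A2 (-9.25), PPP1R9A (-7.98), SEMA3D (-7.98) and C11orf87 (-7.88), and among list members it differed for GATA3 (0.86), GATA4 (3.005), GATA6 (2.98) and, as a fitted value with 1.5 reads in iKC AHDC1 KO, TWIST1 (-5.36).

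Between day 7 AHDC1 KO and hESC GKO, the effects differed for 1680 genes, a count that lay between 936 and 5150 when a single library was left out. It was 5150 without WT hESC replicate 2, 2643 without GKO replicate 2, 966 and 1002 without WT day 7 replicate 1 or 2, and 984 and 936 without AHDC1 KO day 7 replicate 1 or 2. The effect was higher at day 7 for ANKRD1 (6.82), and as fitted values for LINC00261 (9.72), CXCL14 (7.91) and TFAP2B (5.76), each with 0.5 or 0 reads in GKO. It was lower for SHANK1 (-4.53) and DES (-4.39), and as fitted values for KCNJ3 (-8.85) and DLX5 (-8.06), with 0 and 0.5 reads in hESC WT. The CXCL14 call ended without WT hESC replicate 2 (adjusted p = 1), GKO replicate 1 (0.0753) or GKO replicate 2 (0.0513), and the TFAP2B call without WT hESC replicate 1 (0.342), GKO replicate 1 (0.128) or 2 (0.0863), either WT day 7 library (0.0744 and 0.0695) either AHDC1 KO day 7 library (0.0749 and 0.0773) or with the block (0.0517).

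The fall of mesoderm and mesenchyme genes at day 7 was weighed against 2 technical explanations. Scaling of the libraries is argued against, since a factor per library moves every gene alike. Yet the median change of epithelial members at 50 CPM or more lay above that of mesoderm and mesenchyme members. The difference was 1.59 in AHDC1 KO (95% bootstrap interval 1.09 to 1.90) and 1.80 in GATA3 KO (1.30 to 2.38). The bootstrap drew list members, so its interval holds the spread among genes and not among libraries. The lists had been seen to move apart first, so the interval is a description. A lower share of mesoderm cells, with the expression of each cell type unchanged, would raise all epithelial genes alike. Among the 31 epithelial members at 50 CPM or more, the interquartile range of changes was 0.500 in AHDC1 KO and 0.662 in GATA3 KO. Changes ran from DSC3 (-1.04 and -1.56) to CLDN7 (0.93 and 1.19), with a median SE of 0.0378 and 0.0344. Of these members 25 rose and 6 fell in AHDC1 KO, and 26 rose and 3 fell in GATA3 KO. A change of share may be part of the pattern but would leave the members that fell unexplained. Some epithelial genes are also expressed in other cell types, which keeps this open, and an effect of the targeted genes on mesoderm stays open beside it.

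The rise of endoderm genes at day 7 in AHDC1 KO was weighed against 2 explanations. A change shared by every edited line is argued against, since 0% of the endoderm members tested in both comparisons (at most 5) rose in the libraries labelled GATA3 KO. There 3 of the 5 tested fell, and FOXA1 was higher in AHDC1 KO than in GATA3 KO by 5.97 ± 0.16. For endoderm and mesoderm genes alike, a state of the AHDC1 KO line cannot be told from an effect of AHDC1, since the labels give no second AHDC1 KO line. Endoderm-type cells in the AHDC1 KO cultures could bring such transcripts, and of a second list of endoderm genes 37.5% (3 of 8 tested) rose, against 20.9% of all genes. Those 3 (AMBP, MTTP and ONECUT1) stayed under 3 CPM and VTN and CLDN18 fell, so 8 genes are too few to decide. In GATA3 KO 5 genes of this second list were tested, so rises in AHDC1 KO may in part follow from the filter on low counts. The members of the first list were low too, with AFP at 12.2 CPM, FOXA2 at 13.7 CPM and APOB at 13.1 CPM in AHDC1 KO, all named after their values were seen.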

How the results depend on the processing

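No call of a gene or list was replaced by a call in the other direction under any alternative. Of the named gene results, 3905 kept their side of the threshold, 122 lost a call and 8 gained one, and of the list results 985 kept it, 100 lost a call and 49 gained one, counted over all alternatives. Most lost gene calls (89) came from leaving out 1 library, which leaves a group with a lone library assumed to vary like the other groups, then from a fit of all groups (13) and from the block (11).

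Counts of changed genes moved by over 1.5 times as follows, and the cause was not tested unless given. Without a filter on low counts hESC GKO gave 218 genes. A filter of 5 CPM in 2 libraries gave 1652 in iKC, where fewer genes are tested by construction. A fit of all groups gave 1253 in hESC, 2073 (AHDC1 KO) and 3215 (GATA3 KO) at day 7 and 4280 at day 50. DESeq2 gave 4081 and 5244 at day 7 and 3957 between the knockouts, with 2768 genes shared by the day 7 knockouts and 1922 by day 7 and day 50. Asking for at least 2-fold, which can only lower a count, gave 1405, 1890, 2461 and 1349 genes in the comparisons after hESC and 1124 between the knockouts. The stage differences fell to 1200 (day 50 minus day 7), 1332 (iKC minus day 50), 1281 (iKC minus day 7) and 1018 (day 7 minus hESC), and the overlaps to 856 (day 7 knockouts), 455 (day 7 and day 50), 186 (day 7 and iKC), 454 (day 50 and iKC) and 117 (all 3). With an estimated correlation 0 lists were called in each comparison, where camera with the preset correlation had called 7, 14, 12, 13 and 7. With 2 libraries per group that form could hardly call any list, so these losses do not decide whether the lists moved. Fry, which asks whether a list moves on balance and does not compare it with other genes, called 0 lists in hESC, 22 in day 7 AHDC1 KO and 25 in day 7 GATA3 KO.

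Replicate numbers do not pair the libraries: same-numbered libraries deviated from their group means with correlations of -0.302 (hESC), -0.0362 and -0.0384 (day 7), -0.0404 (day 50) and 0.0936 (iKC). In hESC the value was not near 0, so there libraries of opposite number deviated in part alike, and the cause was not tested. With the replicate number as a block 62 genes passed in hESC and 1040 in the difference between day 7 and hESC, and no other count moved as far.

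Leaving out each library gave 49 to 588 genes and 1 to 6 lists in hESC, 5334 to 6268 and 13 to 14 in day 7 AHDC1 KO, 7189 to 7926 and 10 to 14 in day 7 GATA3 KO, 8719 to 9089 and 11 to 13 at day 50, and 583 to 4066 and 4 to 7 in iKC. The knockouts differed in 4994 to 6856 genes, and the stage differences ranged over 1213 to 1296 (day 50 minus day 7), 1509 to 2163 (iKC minus day 50), 1348 to 1829 (iKC minus day 7) and 936 to 5150 (day 7 minus hESC). The share of higher calls in hESC rose from 53.3% to 65.4% with the filter of 5 CPM and to 66.8% without WT replicate 2, and was 42.0% without WT replicate 1, and no scaling moved it as far. At day 50 library-size scaling moved the share of higher calls from 48.5% to 41.5%, and in iKC leaving out either WT library lowered it too. Depth limits the genes near 0, where folds with 3 or fewer reads in a group are no bound. In hESC, where duplicates varied most, 2-fold changes were recovered for 29.9% of simulated genes.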

Other observations

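The tests of explanations for the genes near 0 in GKO hESC were chosen after the result was seen, and the genes of the next paragraph were named after their values were seen.

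The WT iKC libraries held mesenchymal collagen beside almost no vimentin. COL3A1, a fibrillar collagen, stood at 5438 ± 866 CPM in WT iKC and 3454 ± 1045 CPM in AHDC1 KO iKC (-0.68 ± 0.23, edgeR adjusted p = 0.107), while COL1A1 was at 85.8 ± 12.8 CPM and VIM at 0.991 ± 0.111 CPM in WT. At day 50, COL3A1 stood at 21042 ± 511 CPM, COL1A1 at 18217 ± 131 CPM and VIM at 2378 ± 21.6 CPM in WT. FN1, a matrix glycoprotein, fell in AHDC1 KO iKC from 30399.9 ± 4051 to 13620.4 ± 1980.3 CPM (-1.18 ± 0.16, edgeR adjusted p = 0.00475).

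Many of the genes near 0 in GKO hESC were also near 0 in the AHDC1 KO libraries, among them several zinc-finger genes, CAT, MAP10 and TSPYL5, while others were not, with 2 of 14 higher than WT at day 7 and COL3A1 at 14482 CPM at day 50. Loss of wide chromosome segments around most of these genes is argued against, since their 168 nearest tested neighbours had a median change of -0.0566 in GKO hESC. The neighbours were pooled and left out the genes near 0 themselves, so loss of a few segments or of short ones stays open. A change of all these genes in every edited line is argued against too. In the libraries labelled GATA3 KO 5% (1 of 20) were at least 8-fold lower and 17 were above WT. The 1 was CAT (11.9 CPM in WT, 0.443 in GATA3 KO), so for CAT this stays open. Members low in day 7 WT, such as PNPLA4 (14 reads), passed the filter on low counts only through high GATA3 KO counts. Their rise was in part fixed by the filter. That limit does not hold for CSRP1 and ZNF135 (137.5 and 131.5 WT reads), which rose by 5.05 and 1.82. At day 50 75% of the 20 tested genes of this set were at least 8-fold lower in AHDC1 KO. The labels do not say whether the GKO cells and the AHDC1 KO cells come from the same edited line. If they do, a lasting state of that line, carried from hESC on, may account for this as well as an effect of AHDC1 itself. These cannot be told apart because the labels give no second AHDC1 KO line.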
